A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

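RNA of 4 yeast cultures or extracts was measured on 4 one-colour Affymetrix arrays, 2 of wild type (W303-1A) and 2 of the SSG1-1 mutant, as the labels group and number them. Per the labels, strains were kept at 25 °C in rich medium, moved to SDC medium at pH 6.0 and grown for 12 h to early-log phase at 2000000 cells per ml. Per the labels, biotin-labelled cRNA was made from 500 ng of total RNA taken by acid-phenol extraction and purified on columns. The submitters' processing notes name GCOS, Affymetrix's operating software, with no version, and the header of a deposited table names MAS5. The deposited values are signal intensity on a linear scale, 1 value per probe set and array. Background correction and the scaling target are not given in the sources used here.

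The values of all 4 arrays came from the deposited series table, where each column carries a sample's own label. A second deposited table holds MAS5 intensity and detection calls. There, 2 value columns and 2 call columns have headers that name a strain, and both value columns were identical in all 10928 values to replicate 2 of that strain in the series table. The other 4 columns of that table have headers that name no sample or strain and were not used. Detection calls were therefore used from 1 array per strain. The planned filter, present on at least 2 of 4 arrays, was replaced by present in at least 1 of the 2 usable call columns.

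Probe sets were named from the platform annotation and their symbols were updated through the gene identifier against the R64 reference gene table of S. cerevisiae S288C, which changed 12 symbols. Of 10928 probe sets, 5498 were named for 1 S. cerevisiae gene, 1746 for a gene of another organism and 1 for several genes, while 3470 had no name here and 213 were controls. The filter removed 122 and left 5376 probe sets for 5330 genes. Where a gene had several probe sets, the one with the highest mean log2 signal stood for it. No coordinates are given, because the files name no genome build.

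The design, fixed before the data were examined, used the values as deposited unless the arrays had not been scaled alike, in which case quantile normalization came first. The 2% trimmed mean signals were 1298 and 1122 in the wild type and 1034 and 1168 in the mutant, so the arrays had not been brought to 1 level and quantile normalization of log2 signal was applied. Signals below 0.1 were set to 0.1 before log2. All signals and differences in the report are after this step unless called deposited. The median log2 difference, mutant minus wild type, over all tested probe sets was -0.02 after normalization and -0.15 in the deposited values, so changes are relative to that shift.

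Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend), 2 arrays against 2, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors are limma's moderated standard errors. The 41 gene lists were fixed before the data were examined, and 7 of their names were not found in the reference. They were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Camera compares a list with the other genes, and fry asks whether its genes move one way on balance. Counts within a list were also adjusted over the list alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

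Genes were named by a rule fixed beforehand. In each direction it takes the 10 largest log2 differences past the adjusted threshold, with no overlap between strains, a present call in the higher strain and a standard symbol. Where fewer than 5 pass, it takes the 10 largest at an unadjusted p under 0.05. It adds up to 2 members per list past the adjusted threshold, and it always names a set of methionine cycle genes, SNF1, SIR2, SPR1, the W303 markers and the mating-type genes. TRP1 had no named probe set. Because a single gene passed, up to 2 members of each list past camera were named from the fit with a replicate block. That step, which was chosen after values were seen, covers the list examples in the report.

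Replicate numbers were checked for pairing. Same-numbered arrays deviated together from their group means (correlation 0.634 across probe sets). The labels do not say what a number marks and there are only 2 pairs, so the main fit has no block, and the blocked fit is given in the closing section.

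The fits were tested on simulated data for the comparison of mutant with wild type, in 10 runs of 5376 probe sets, 200 of them changed. The simulation used the probe sets' mean signals, with variances drawn at random around the mean-variance trend of the fit without a block. With independent arrays, the fit without a block recovered 42.5% of changes of 1 log2 unit and 86.3% of changes of 2 log2 units, with 8.8 false calls per run. Where same-numbered arrays shared their deviations, it recovered 41.2% and 84.1% with 2.4 false calls per run, and the blocked fit 80.6% and 96.4% with 17.4. A list of 40 genes shifted by 0.3 had a camera p under 0.05 in 10 of 10 runs, both with the preset and with the estimated correlation. The simulated genes varied independently of each other, apart from the shared change, so this does not test lists whose genes vary together. Recovery past an adjusted threshold also depends on how many genes change, and fewer than 200 were not simulated. On the measured arrays, HXK1, TMA10 and HXT7 had differences above 2 log2 units and did not pass.

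Alternatives were values as deposited, median centring, cyclic loess, no detection filter, a stricter filter, a floor, a pseudocount of 32, no trend, a robust variance, a replicate block, each array left out, other thresholds, a 2-fold rule between every pair of arrays, an estimated correlation and the mean of a gene's probe sets. Values as deposited, presence in both call columns and the block without a trend were added after the data were seen.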

Results

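Gene expression was measured in budding yeast with Affymetrix arrays in 2 strains, the laboratory strain W303-1A (wild type) and the long-lived SSG1-1 mutant. Each strain had 2 arrays, numbered 1 and 2. Cells had been grown in synthetic SDC medium at pH 6.0 to early-log phase before total RNA was taken. The labels do not say whether the 2 arrays of a strain came from separate cultures. The p-values of single genes therefore measure only the spread between these arrays, which may be technical. Camera with the preset correlation instead judges a list by the spread across genes. It takes the correlation between genes as given. Its p-values therefore leave out how far the genes of a list vary together between these arrays. The median deposited signal of the probe sets for S. cerevisiae genes was 1171 and 1012 in the wild type and 874 and 1084 in the mutant. Probe sets for genes of another yeast on the same array had medians of 5 and 4.8 in the wild type and 5.05 and 5.3 in the mutant. Having 2 arrays per strain limits the precision, and the median standard error of a log2 difference was 0.163.

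The arrays correlated across genes with Pearson's r of 0.985 between the wild-type arrays and 0.983 between the mutant arrays, where genes are not independent replicates. Arrays of different strains with the same number correlated more closely, at 0.989 for number 1 and 0.991 for number 2. Their median absolute log2 difference was 0.136 and 0.128, against 0.184 between the wild-type arrays and 0.193 between the mutant arrays. The first principal component, with 58.6% of the variance, placed both arrays numbered 1 on one side (-8.14 and -17.0) and both arrays numbered 2 on the other (15.3 and 9.81). Split by number in place of strain, the same limma test called 160 probe sets at an adjusted p under 0.05. Differences within each number are therefore given beside the gene lists that passed camera.

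The comparison of mutant with wild type addressed which genes are expressed differently in a long-lived SSG1-1 strain. HRI1 (YLR301W), a gene of uncharacterized function, rose 9.18-fold in the mutant. Its signal was 922 and 716 on the wild-type arrays and 7167 and 7760 on the mutant arrays (log2 difference 3.20 ± 0.16 SE, n = 2 per strain, limma adjusted p = 0.0349). It was the only probe set of 5376 past the adjusted threshold, and 0 probe sets fell. At an unadjusted p under 0.05, limma gave 146 probe sets higher and 97 lower. Both mutant arrays lay above both wild-type arrays for 754 probe sets and below them for 968. Of these, 22 were at least 2-fold higher and 8 at least 2-fold lower. Chance would give 16.7% in each direction if all arrays varied alike and independently. Same-numbered arrays deviated together (correlation 0.634), so that share does not apply here and the counts cannot be judged against it. The call of HRI1 ended without the mean-variance trend (adjusted p = 0.203), with its log2 difference at 3.20 in both fits.

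The other 9 genes named as higher by a rule fixed beforehand did not pass the adjusted threshold. The rule itself takes only genes whose arrays do not overlap between strains. HXK1, the hexokinase made when glucose is low, was 7.59-fold higher in the mutant (log2 2.92 ± 0.26 SE, n = 2 per strain, limma adjusted p = 0.214). The hexose transporter genes HXT7 and HXT4 had log2 differences of 2.26 ± 0.21 and 1.97 ± 0.22 (SE). The probe set for HXT7 is of a type that can match close paralogs, so its value is uncertain for HXT7 alone. ADR1, a transcription factor for glucose-repressed genes, stood at 1.68 ± 0.22, and MTH1, a regulator of hexose transporter genes, at 1.65 ± 0.23. TMA10 was at 2.40 ± 0.50, ATG39, a receptor for autophagy of the nuclear envelope, at 1.62 ± 0.32, MHT1, a homocysteine methyltransferase, at 1.39 ± 0.21, and GTO3, a glutathione transferase, at 1.26 ± 0.23. The wild-type signals of TMA10 (67.2 and 29.0), MTH1 (68.5 and 89.3) and GTO3 (46.1 and 52.5) were near the dim end of the arrays. With the values as deposited, HXK1, TMA10, HXT7, HXT4 and ADR1 also passed the threshold. In that fit limma took each gene's variance from the mean-variance trend alone, so the spread of the gene's own arrays did not enter.

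**Figure D1:**
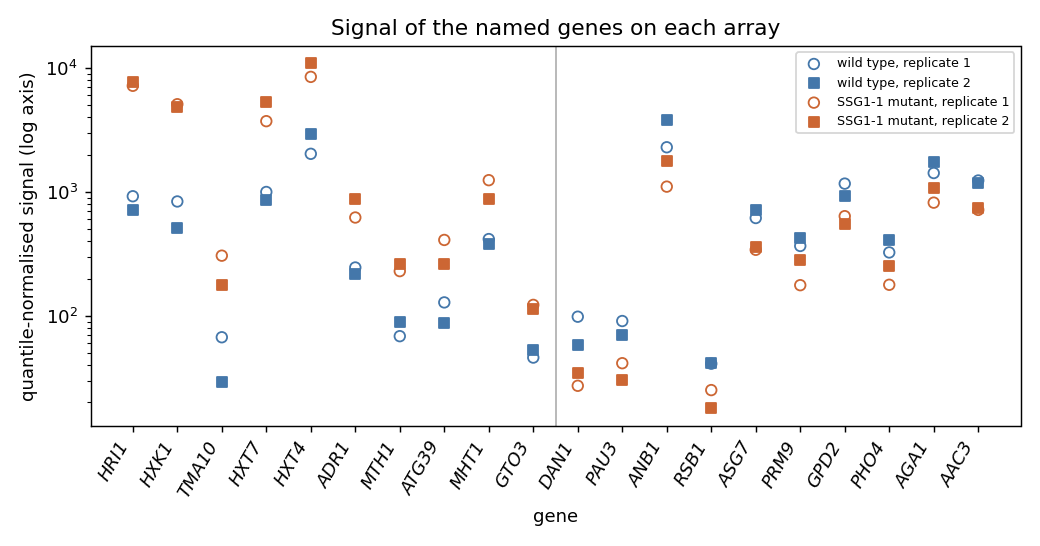
Quantile-normalised signal (log axis) of the 10 genes named by the rule as higher (left of the line) and the 10 named as lower (right) on each of the 4 arrays. Each point is 1 array. The mutant points of HRI1 lie at 7167 and 7760, above the wild-type points at 922 and 716.

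On the lower side no gene passed the adjusted threshold. The 10 genes named by the rule, which asks for a standard symbol, ran from DAN1 at log2 -1.30 ± 0.37 (SE) to AAC3 at -0.73 ± 0.13. YBL071C-B, which has no such symbol and was picked out after its value was seen, lay lower at -1.77 ± 0.35. DAN1, PAU3 (-1.18 ± 0.31), ANB1 (-1.07 ± 0.34) and AAC3 are genes made mainly when oxygen is scarce. The probe set for PAU3 is of the type that can match close paralogs, so its value is uncertain for PAU3 alone. DAN1 had signals of 98.4 and 58.2 in the wild type and 27.3 and 34.5 in the mutant, near the dim end of the arrays. PAU3 (90.8, 70.6, 41.5 and 30.1 in the same order) and RSB1 (41.1, 41.4, 25.2 and 17.9) were there too. ANB1 was brighter and went from 2289 and 3807 to 1102 and 1786. RSB1 was at -0.96 ± 0.35, the glycerol-3-phosphate dehydrogenase gene GPD2 at -0.82 ± 0.18, and PHO4, the activator of phosphate genes, at -0.78 ± 0.24. The mating genes ASG7 (-0.91 ± 0.15), PRM9 (-0.82 ± 0.27) and AGA1 (-0.73 ± 0.20) were in the same range.

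3 lists of mitochondrial energy metabolism were higher in the mutant by camera with the preset correlation. None of them passed with an estimated correlation (adjusted p = 0.391 for each) or with fry (limma adjusted p between 0.135 and 0.245). Of 42 measured genes of the respiratory chain and ATP synthase, 37 had both mutant arrays above both wild-type arrays and 2 had both below. Their median log2 difference was 0.32, at 0.27 within number 1 and 0.31 within number 2, and 21 members passed when adjusted over the list alone (0 over all genes). INH1, the inhibitor of the mitochondrial ATPase, was at 0.98 ± 0.10 (SE) and HAP4, the activator of respiratory genes, at 0.64 ± 0.18. The list rose against the other genes in limma's camera test (adjusted p = 2.03e-28). Mitochondrial ribosomal protein genes had a median of 0.19, with 41 of 66 higher on both mutant arrays and 2 lower (0.14 and 0.21 within numbers 1 and 2). Examples were RSM23 at 0.46 ± 0.13 and MRPL3 at 0.42 ± 0.10. The camera adjusted p was 1.87e-12. The tricarboxylic acid cycle list had a median of 0.18 over 23 genes, 11 of them higher on both mutant arrays and 2 lower, with SDH2 at 0.67 ± 0.10 and CIT3 at 0.67 ± 0.35. The median was 0.18 within number 1 and 0.17 within number 2. Here 3 members passed adjusted over the list alone, and the camera adjusted p was 1.15e-06.

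Genes repressed by glucose had a median log2 difference of 0.46 over 28 measured genes, of which 14 were higher on both mutant arrays and 1 lower. HXK1 and ADR1 led the list, and 4 members passed adjusted over the list alone. The median was 0.36 within number 1 and 0.65 within number 2. The list also differed between the numbers themselves, by 0.29 for number 1 over number 2. Camera gave an adjusted p of 4.47e-12, and 0.567 with an estimated correlation. Hexose transport genes had a median of 0.29 over 16 genes, 8 higher on both mutant arrays and 4 lower, with 4 past the threshold adjusted over the list alone. The medians within numbers 1 and 2 were 0.23 and 0.24. The camera adjusted p was 0.000486, and 0.567 with an estimated correlation. Trehalose and glycogen genes had a median of 0.18 over 18 genes, with GSY1 at 0.81 ± 0.24 and GPH1 at 0.70 ± 0.35 and medians of 0.17 and 0.14 within the numbers (camera adjusted p = 0.00155, and 0.503 with an estimated correlation).

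Sulfate assimilation and methionine synthesis genes, which supply the sulfur amino acids, had a median log2 difference of 0.40 over 27 genes. Both mutant arrays were higher for 11 of them and lower for 0. MET2 was at 1.30 ± 0.58 (SE) and MET14 at 1.12 ± 0.51, and neither passed the threshold. The median was 0.46 within number 1 and 0.15 within number 2, and the list was 0.28 higher in number 1 than in number 2 across strains. Its camera adjusted p was 8.6e-07, and 0.567 with an estimated correlation. Of the always-named genes in the list for the S-adenosylmethionine cycle and its use, SAM1 was at 0.06 ± 0.06, SAM2 at -0.01 ± 0.11 and SAH1 at 0.13 ± 0.07. MET6 was at 0.15 ± 0.07, ADO1 at -0.10 ± 0.07 and ERC1 at -0.30 ± 0.14. Both mutant arrays lay above both wild-type arrays for SAM1, SAH1 and MET6 and below them for ADO1 and ERC1, while SAM2 overlapped. The signs of SAM1 and SAM2 depended on the scaling. The list for S-adenosylmethionine use had a median of -0.02 over 20 genes (camera adjusted p = 0.879), with 1 member, MHT1, past the threshold adjusted over the list alone. The methionine permease gene MUP1 was at 0.12 ± 0.14, positive after normalization and negative in the deposited values.

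The iron regulon had a median log2 difference of 0.14 over 30 genes, with the cell wall genes FIT2 at 1.02 ± 0.30 (SE) and FIT3 at 0.75 ± 0.17. The median was 0.23 within number 1 and 0.10 within number 2. Split as mutant 1 and wild type 2 against the other arrays, the list also passed camera, with a median of 0.07 (adjusted p = 0.0310). Between strains its camera adjusted p was 4.85e-05, and 0.567 with an estimated correlation. Its median was -0.01 in the deposited values, where all genes had a median of -0.15. General stress genes had a median of 0.09 over 42 genes (RIM4 0.79 ± 0.27, MSN4 0.67 ± 0.21). Of the 42, 7 were higher on both mutant arrays and 3 lower, against 754 and 968 of all 5376 tested probe sets. The medians within numbers 1 and 2 were 0.10 and 0.04, and the difference between numbers was larger, at 0.31 for number 1 over number 2. Without mutant replicate 1 their median was -0.09. Oxidative stress genes had a median of 0.08 over 31 genes, with PRX1 at 0.74 ± 0.32 and CCS1 at -0.70 ± 0.17, and medians of 0.05 and 0.08 within numbers 1 and 2. The difference between numbers was larger here too, at 0.15 for number 1 over number 2. In the deposited values their median was -0.06. The camera adjusted p was 0.0349 for general stress and 0.0386 for oxidative stress, and 0.828 and 0.755 with an estimated correlation.

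**Figure D2:**
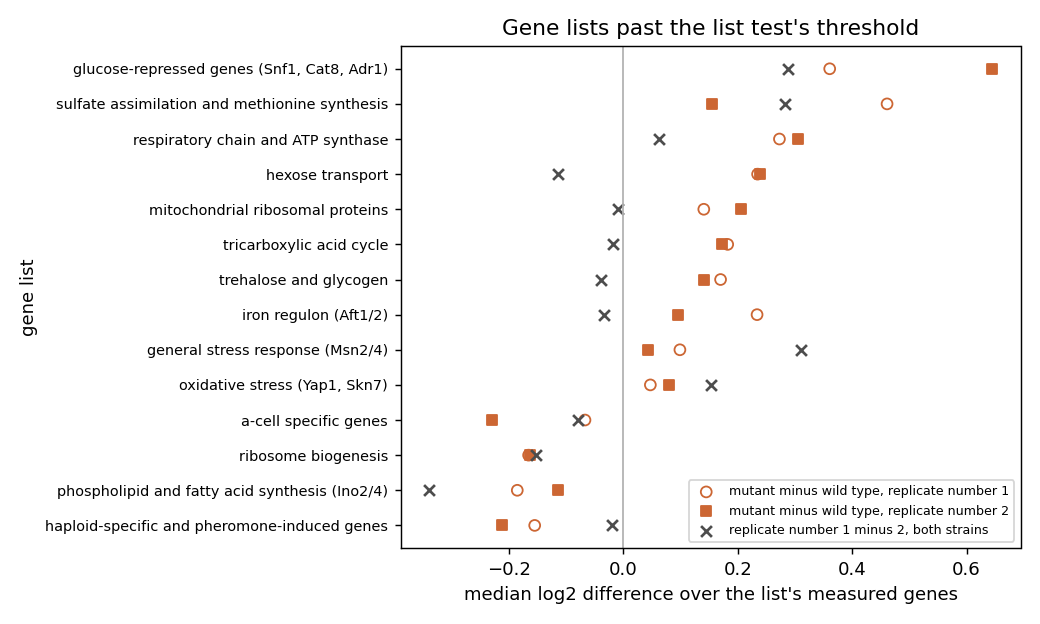
Median log2 difference (horizontal axis) over the measured genes of each of the 14 gene lists past the camera threshold (vertical axis). Circles give mutant minus wild type within replicate number 1, squares the same within number 2, and crosses number 1 minus number 2 over both strains. The respiratory chain list lies at 0.27 and 0.31 with its cross at 0.06, and the general stress list at 0.10 and 0.04 with its cross at 0.31.

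4 lists were lower in the mutant by camera. Ribosome biogenesis genes had a median log2 difference of -0.16 over 67 genes, 25 of them lower on both mutant arrays and 2 higher, with MAK16 at -0.52 ± 0.20 (SE) and NOP8 at -0.34 ± 0.14. Its medians were -0.17 and -0.16 within numbers 1 and 2, and the list was also at -0.15 for number 1 minus number 2. Its camera adjusted p was 2.32e-07, and 0.657 with an estimated correlation. Haploid-specific and pheromone-induced genes had a median of -0.18 over 25 genes, 10 lower on both mutant arrays and 0 higher, among them AGA1 and FUS1 (-0.63 ± 0.14). Their medians were -0.16 and -0.21 within numbers 1 and 2 and -0.02 between numbers. The camera adjusted p was 0.000878, 0.503 with an estimated correlation, and 0.0971 with fry. The genes specific to a-mating-type cells had a median of -0.14 over 8 genes, at -0.07 and -0.23 within numbers 1 and 2 (camera adjusted p = 0.0348, and 0.688 with an estimated correlation). ASG7 (-0.91 ± 0.15) led the list and was its only member past the threshold adjusted over the list alone. AGA2 stood at -0.29 ± 0.10, BAR1 at -0.36 ± 0.25, STE6 at -0.17 ± 0.13 and STE2 at -0.11 ± 0.05. AXL1 was at 0.02 ± 0.29, MFA1 at 0.23 ± 0.19 and MFA2 at 0.01 ± 0.06. AXL1 and MFA2 were negative in the deposited values. Phospholipid and fatty acid synthesis genes had a median of -0.18 over 26 genes, with CPT1 at -0.30 ± 0.12 and FAS2 at -0.16 ± 0.07, and stood at -0.19 and -0.12 within numbers 1 and 2 and at -0.34 between numbers. The camera adjusted p was 0.00352, and 0.755 with an estimated correlation. Without mutant replicate 1 the median was 0.02.

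Genes specific to either mating type were compared between the strains. STE2, the receptor for alpha-factor, had signals of 13837 and 13873 in the wild type and 12655 and 12992 in the mutant. MF(ALPHA)1, which encodes alpha-factor, had signals of 31.2 and 54.9 in the wild type and 17.9 and 39.6 in the mutant. In the same order, the other genes specific to alpha cells had signals of 48.0, 58.9, 56.3 and 110.2 (STE3), 70.0, 95.4, 80.4 and 71.2 (MF(ALPHA)2), 758, 1236, 878 and 961 (SAG1) and 1964, 2185, 1333 and 1903 (AFB1). Levels of different probe sets cannot be compared. The list of genes specific to alpha cells had a median log2 difference of -0.11 over 5 genes (camera adjusted p = 0.668), with STE3 at 0.57 ± 0.40 (SE), MF(ALPHA)1 at -0.63 ± 0.54, MF(ALPHA)2 at -0.11 ± 0.27, SAG1 at -0.08 ± 0.26 and AFB1 at -0.38 ± 0.21. MF(ALPHA)2 was positive with median centring. The auxotrophy and marker genes of W303 had a median of -0.05 over 8 genes. They were ADE2 at -0.07 ± 0.16, HIS3 at -0.12 ± 0.21, LEU2 at 0.06 ± 0.27, URA3 at 0.03 ± 0.24, CAN1 at -0.04 ± 0.22, SSD1 at -0.04 ± 0.17, RAD5 at -0.05 ± 0.15 and YBP1 at -0.08 ± 0.22, and the signs of LEU2 and URA3 depended on the scaling. The probe-set annotation used here names no gene SSG1. The reference gives SSG1 as an older name of SPR1 (YOR190W), which may not be the mutated gene, and SPR1 was at 0.14 ± 0.28 with overlapping arrays. SNF1, the kinase needed for growth without glucose, was at 0.05 ± 0.19, negative in the deposited values, and the histone deacetylase gene SIR2 at -0.25 ± 0.18.

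The remaining lists did not pass camera at an adjusted p under 0.05. Subtelomeric families had a median log2 difference of 0.19, the phosphate regulon 0.17, nitrogen catabolite repression 0.09, thiamine, biotin and pyridoxine 0.08, autophagy and vacuolar proteases 0.07, meiosis and sporulation 0.06, glycolysis and fermentation 0.05 and heat shock 0.04. The phosphate regulon differed more between numbers, at 0.47 for number 1 over number 2. With a replicate block it passed camera (adjusted p = 7.39e-07), but not with the block and an estimated correlation (camera adjusted p = 0.729). Zinc and copper response genes had a median of -0.10, drug efflux -0.08, the proteasome -0.06, NAD synthesis and sirtuins -0.06, pyrimidine synthesis -0.05, G2/M cell cycle -0.04, amino acid permeases -0.04, the vacuolar ATPase -0.03, G1/S cell cycle -0.03 and amino acid biosynthesis -0.02. Calcineurin targets were at 0.02, cell wall integrity at 0.01, core histones at 0.0079, ergosterol synthesis at 0.0071, purine synthesis at 0.0034 and cytosolic ribosomal proteins at -0.00023. Several of the medians near 0 took the opposite sign from the mean or from the direction of the test, among them ribosomal proteins, core histones, purine synthesis and NAD synthesis. 0 of the 41 lists passed with fry, and 0 with camera and an estimated correlation.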

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

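All tests of explanations in this part were chosen after the result each measures was seen.

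Outside the tested genes, 16 probe sets were called present in the mutant and at least 2-fold higher on every mutant array than on every wild-type array. They were 12 without a gene name here, 3 of another organism and 1 control. They were picked from 5430 probe sets the comparison did not use, of which 860 were called present in either usable column. Only probe sets higher in the mutant were searched for. Their highest signal on a mutant array was 22.8, near the dim end of the arrays. What they measure was not tested.

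HRI1 was the only gene past the threshold with the settings of the report, and other fits without a block called between 0 and 6 genes higher. A change of the chromosomal segment around it would move its neighbours, but among 8 measured genes of the 12 nearest on both sides the largest absolute log2 change was 0.495 (ATP14), against 3.20 for HRI1. A single aberrant array was also excluded, since the lowest of the 4 values without 1 array was 3.02. A mutation at HRI1 itself, another effect of the SSG1-1 genotype, and a difference between these samples were not tested.

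The respiratory chain and ATP synthase list was higher in the mutant by camera with the preset correlation, but passed neither with an estimated correlation (limma adjusted p = 0.391) nor with fry (limma adjusted p = 0.245). A difference between the replicate numbers that is alike in both strains cancels, as each strain holds both numbers. The medians within a number therefore do not test it. The list's smaller median within a number was 0.273 (95% bootstrap interval 0.211 to 0.365 over its genes). That interval leaves out the spread between arrays. As for scaling, the list's median minus that of all genes was at least 0.319 under 4 scalings. The rise against other genes thus did not depend on the choice among them. A factor shared by all genes of an array cancels in this measure, so such a factor was not tested. Variation of single arrays stays open: the crossed split, mutant 1 and wild type 2 against the others, moved the list by -0.0217 against 0.317 between strains. This ratio passed the limit set first, the 5% critical value of t on 1 degree of freedom. That limit was made stricter, for the 41 lists this one leads, after the ratio had been seen, and the ratio did not pass it. On 1 degree of freedom so strict a limit is hard for any list to pass, so failing it decides nothing. Less glucose in the mutant cultures at harvest could also raise such genes and stays open beside the genotype, as HXT1 and HXT3, transporters made at high glucose, averaged -0.0011 with 1 below and 1 above 0.

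Of the lists past camera that also differed between the replicate numbers, 2 were examined further. Ribosome biogenesis, phospholipid synthesis, general stress and oxidative stress differed between numbers too and were not examined in this way. A difference alike in both strains cancels between them, so the medians within a number do not test it. The smaller median within a number was 0.361 (0.178 to 0.661) for the glucose-repressed list and 0.155 (0.0199 to 0.521) for the sulfate assimilation and methionine list. The crossed split moved them by -0.0622 and 0.0761, against 0.457 and 0.404 between strains, and the split itself passed limma's camera test for 5 of the 41 lists. These were the phosphate regulon (limma adjusted p = 0.00919), G1/S (0.00919), the iron regulon (0.031, median 0.068 against 0.144 between strains), G2/M (0.0331) and the sulfate list (0.0471). Variation of single arrays and an effect of the genotype cannot be told apart for the glucose-repressed and sulfate lists, because the crossed split is the only contrast left to measure it with 2 arrays per strain.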

How the results depend on the processing

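With 1 gene higher and 0 lower, the gene counts moved with many settings, and the cause was not tested unless stated. Genes higher numbered 6 with values as deposited, 4 with median centring, 0 without a trend, 0 at a threshold of 0.01 and 1 to 4 with an array left out. The last range leaves 1 array in a strain, which is assumed to vary like the other strain's. The 2-fold rule, which makes no test, gave 10 higher and 1 lower (YBL071C-B, named after its value was seen). With a replicate block there were 427 higher and 401 lower, but the block leaves 1 residual degree of freedom. There, and with values as deposited, limma took each gene's variance from the mean-variance trend alone. Without a trend the block gave 3 higher (HRI1, HXT4, ATG39) and 1 lower (YBL071C-B). Beside the 0 lower, limma gave 97 at an unadjusted p under 0.05. Of the 14 lists past camera, the 10 higher became 16 with median centring, and both the 10 higher and the 4 lower became 0 with an estimated correlation. All 14 remained called with median centring, cyclic loess, both filters, the floor, the pseudocount and the robust variance, 13 with values as deposited and 12 with the replicate block, where general stress and oxidative stress no longer passed, and between 10 and 14 with an array left out. General stress, oxidative stress, phospholipid synthesis and a-cell genes no longer passed without wild type replicate 2 or without mutant replicate 1, and a-cell genes also without mutant replicate 2. Without a trend, oxidative stress and a-cell genes no longer passed. Both tables hold the same values for the arrays they share, so the planned exchange of tables was not run, and presence on all 4 arrays was not run because 2 call columns were usable. Signal over background limits the dim genes such as DAN1.

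With values as deposited, where all genes have a median of -0.15, these signs turned: SAM1 -0.053, MUP1 -0.054, SNF1 -0.097, MFA2 -0.0695, LEU2 -0.067, URA3 -0.15, AXL1 -0.147, and the list medians of glycolysis -0.025, heat shock -0.0897, oxidative stress -0.056, purine synthesis -0.105, iron regulon -0.011, ergosterol -0.102, calcineurin -0.132, cell wall -0.103, autophagy -0.048, nitrogen catabolite repression -0.043, histones -0.0765 and thiamine -0.054. With median centring they were MF(ALPHA)2 0.031, URA3 -0.00195, SAM2 0.078, ribosomal proteins 0.089, amino acid biosynthesis 0.0014 and permeases 0.0021. With cyclic loess they were SAM2 0.0071 and ribosomal proteins 0.021. Of these uncalled lists, camera called ribosomal proteins with median centring (adjusted p = 0.00144) and autophagy with values as deposited (adjusted p = 0.0155).

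With an array left out, signs turned for 2 called lists, general stress (-0.0900 to 0.295) and phospholipid synthesis (-0.291 to 0.023). Of uncalled genes, the ranges were ADE2 -0.194 to 0.063, AXL1 -0.283 to 0.322, CAN1 -0.259 to 0.183, HIS3 -0.323 to 0.0898, LEU2 -0.289 to 0.414, MF(ALPHA)2 -0.323 to 0.108, MFA2 -0.0081 to 0.0385, MUP1 -0.026 to 0.265, SAG1 -0.427 to 0.278, SAM2 -0.137 to 0.121, SNF1 -0.102 to 0.211, SPR1 -0.038 to 0.311, SSD1 -0.1997 to 0.106, URA3 -0.317 to 0.359 and YBP1 -0.339 to 0.178. Of uncalled lists, they were G1/S -0.113 to 0.051, NAD synthesis -0.0476 to 0.024, S-adenosylmethionine -0.116 to 0.037, W303 markers -0.133 to 0.014, alpha-cell -0.427 to 0.108, amino acid biosynthesis -0.062 to 0.035, permeases -0.039 to 0.018, calcineurin -0.029 to 0.0043, cell wall -0.0092 to 0.0095, histones -0.036 to 0.011, ribosomal proteins -0.0066 to 0.0096, drug efflux -0.161 to 0.012, ergosterol -0.028 to 0.049, glycolysis -0.012 to 0.082, heat shock -0.036 to 0.0701, meiosis -0.014 to 0.088, nitrogen catabolite repression -0.093 to 0.165, phosphate -0.182 to 0.511, purine synthesis -0.054 to 0.018 and thiamine -0.046 to 0.224.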

Other observations

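The test in this part was chosen after the result was seen. DAN1, PAU3, ANB1 and AAC3, all lower in the mutant though none passed the adjusted threshold, are genes made mainly when oxygen is scarce, although the probe set for PAU3 can match close paralogs. A hypothesis was that oxygen-repressed genes were lower as a group. Among 26 other genes linked to low oxygen, listed after these 4 had been seen, the median log2 difference was 0.013 (95% bootstrap interval -0.0798 to 0.101), with 3 higher and 6 lower on both mutant arrays. The list holds ROX1, a repressor of such genes that is itself made with oxygen, and over the other 25 the median was 0.0074 (-0.101 to 0.101). YHK8 at -0.707 and TIR1 at -0.511, named after their values were seen, lay near the range of the 4 genes. Camera on that list gave an unadjusted p of 0.91. A fall of the size seen in AAC3 (-0.733) in most genes of this list is therefore argued against. The intervals leave out the spread between arrays, and a median does not test a fall of only some of the genes. Whether the 4 genes, picked from the low extreme of 5376 probe sets, differ between the strains stays open.

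Median log2 differences of the 16 chromosomes lay between -0.0398 and 0.0218. In 8 control probe sets for 25S ribosomal RNA, deposited signals were higher in number 1 than number 2 by a median log2 of 0.533. Their median of mutant minus wild type was -0.219, against -0.15 over all tested probe sets in the deposited values. Over the 8 probe sets the difference between numbers ran from -0.0412 to 1.32.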
